A study of Mus musculus with 26 samples.

How the data were processed

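Single-cell suspensions of mouse embryos at embryonic day 12.5, of Xbp1 knockout (KO) and wild-type (WT) genotype, were made into Microwell-seq libraries, per the labels' protocols. The data used were 26 count tables, 15 KO and 11 WT, and a table that gives each cell's library and cluster number. The authors deposited whole-number counts per gene and cell, which were taken as UMI counts, with no normalization. Reads had been aligned with STAR to GRCm38, per the submitters' processing notes; the STAR version, the barcode and UMI handling, the filter on cells and the clustering tool are not given in the sources used here. The deposited cluster table holds 27 cluster numbers without names. Each cell of the count tables appears in that table, so that adding cells outside the annotation changes nothing. A source unit whose libraries are not all among these 26 was used with those it has; any other library was not analysed here.

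The shallowest cell held 561 UMIs, so a minimum near that depth sets which cells enter the shares of cells. No doublet caller was run and the sources do not say whether doublets had been removed, so cells holding RNA of more than 1 type stay in the sums. Libraries of a source unit (KO1 to KO5, WT1 to WT4) were summed. Pairs of libraries were compared by a chi-square test over genes with at least 20 counts, to look for a library deposited more than once. Chi-square per degree of freedom was 1.60 to 12.7 (median 4.73) in 27 pairs of a source unit and 3.42 to 60.2 (median 15.6) in 133 pairs of other units of the same group, with a p over 0.05 in 0 pairs. The sequencing run was read from the date string in the cell names. Symbols were used as given in the files, and positions were taken from GENCODE release M21 for GRCm38. Counts of genes with near-identical copies, such as the globins, the Serpina1 genes and the class I gene H2-Q10, are uncertain, since how the authors split shared reads is not given.

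Clusters were named from marker lists fixed before the data were examined. A marker counted for a cluster when its level, after adding 20 CPM, was at least 1 log2 unit above the mean of the other clusters and at least 50 CPM, and a name needed at least 5 such markers with at least 1 of its list among the 10 leading genes and more there than any other list. The minimum of 5 was raised from 3 after clusters had been seen, which kept cluster 10 (1.33% of KO and 4.00% of WT cells) out of the granulocyte-like name. A cluster with over 75% of its cells from 1 source unit stayed unnamed, as cluster 15 did. Names are written as X-like, and clusters were compared by number.

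Counts were summed per source unit over all cells, and within each cluster over units with at least 20 cells, where each group had at least 3 such units. They were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. Numbers of cells per cluster were tested with the same tool, with the unit's total cells as library size, for clusters of at least 50 cells. In all, 36 gene lists fixed before the data were examined were tested where at least 3 members were measured, with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, an estimated correlation and fry. The lists covered the 3 branches of the unfolded protein response, transcripts cut by IRE1, cell type markers, cell cycle, metabolism, dissociation stress, mitochondrial and sex-linked genes and genes of body position. Genes were named by a rule fixed before the data were examined: the 12 largest rises and falls of the whole embryo with an average of at least 10 CPM, the 4 largest each way with at least 20 CPM in the 6 clusters with most calls (10 or more), and the 4 smallest p-values of each list described. Gene models without a name were counted and not named. Results of some single genes are not reported here.

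Scores of the 3 stress lists were the mean of log2(CPM + 1) per source unit. Scores, shares of UMIs and genes per cell, after thinning each cell to 500 UMIs, were compared by exact permutation tests, two-sided, with scipy 1.17.1; 126 splits of 5 against 4 units give a p of at least 0.0159 and 35 splits of 3 against 4 at least 0.0571. In the hepatocyte-like cluster a ratio from 1 to 3 counts is given with its exact 95% interval, which covers counting error only.

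The steps were tested on simulated data, with the changed genes drawn from those with at least 10 CPM. No difference between runs was simulated, so recovery of genes at lower levels or under such a difference was not tested. For the whole embryo, 28%, 82%, 98% and 100% of genes changed 1.5-, 2-, 4- and 8-fold were recovered among 15663, with 9 false calls. For the hepatocyte-like cluster, 4%, 34%, 80% and 88% were recovered among 4004 genes, with 4 false calls. An 8-fold lower cluster was recovered in 96% of 200 simulated tables of 27 clusters, with 0.08 false calls per table.

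Alternatives fixed before the data were examined were size factors by RLE, DESeq2 1.42.0, no filter on low counts, erythroid-like clusters or globin genes left out, libraries as units with the source unit as a random block, the source number as a block, WT1 and WT2 left out, each source unit left out in turn, at least 50 cells per unit, TMM over clusters and an exact permutation test for the shares of cells, log2(CPM + 10) for the scores, and thinning to 300 or 1000 UMIs. Added after the data had been examined were run as a term, values within runs, the units with Y-linked RNA alone, at least 10 cells per unit, the share of cells by UMIs of hepatocyte genes, and genes per cell without erythroid-like clusters. Other splits of the units were drawn 100 times; for the other clusters that number was raised from 20, by way of 40, after the earlier results had been seen. Splits within runs were added after the data had been examined.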

Results

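Single cells of C57BL/6 mouse embryos at mid-gestation (E12.5) were profiled by Microwell-seq, a method in which dissociated cells settle into small wells holding barcoded beads and transcript ends are counted with unique molecular identifiers (UMIs). Embryos with a knockout of Xbp1 (KO) were compared with wild-type embryos (WT). XBP1 is a transcription factor of the unfolded protein response, made active when the endoplasmic reticulum (ER) sensor IRE1 splices its mRNA, and the comparison asks which cells and genes of the embryo differ without it. The data held 93246 cells, 49498 KO and 43748 WT, from 26 libraries prepared from 9 source units, KO1 to KO5 and WT1 to WT4. Libraries held 1277610 to 6825945 UMIs each, and source units held 4052514 to 23850142. The median cell had 988 UMIs and the shallowest 561. Median UMIs per cell were 988 ± 90.9 (SD, n = 5) in KO and 994 ± 65.4 (SD, n = 4) in WT units. The source unit was the replicate throughout, and since the labels do not say that a source is 1 embryo, p-values measure the spread between these units. Cells came from 3 sequencing runs. The first held WT1 and WT2 alone, the second KO1, KO2 and WT3, and the last KO3, KO4, KO5 and WT4, so values with run as a term, or within the second and last runs, stand beside many of the pooled ones. The stress scores and genes per cell were compared without a term for run. A gene or list given without a value for run rests on the pooled test. With run as a term the difference between the groups rests on WT3 and WT4 as the WT units, since the first run holds no KO unit. Those values are thus not separate from the ones without WT1 and WT2. The first principal component of the whole-embryo profiles, with 49.5% of the variance, set WT1 and WT2 apart from the other units. WT1 and WT2 also differed in cell makeup. Cluster 9, led by embryonic globins, held 0.020% and 0.028% of their cells and at least 0.917% in every other unit. Granulocyte-like cluster 25 held 1.06% and 1.15% of their cells and at most 0.246% in every other unit. Run cannot be told apart from other differences of WT1 and WT2, which the pooled values include. KO1 and KO2 carried Xist RNA (193 and 212 CPM) and no counts of the Y-linked Ddx3y, while the other 7 units carried Ddx3y RNA and at most 0.08 CPM of Xist.

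Xbp1 RNA itself was present in both groups and did not pass the test. The level of Xbp1 (chromosome 11, 5520659 to 5525893, plus strand, ENSMUSG00000020484.18, GRCm38) was 58.7, 74.3, 108, 105 and 91.6 CPM in KO1 to KO5 and 123, 91.8, 77.9 and 114 CPM in WT1 to WT4, from 5291 KO and 5264 WT counts. The log2 fold change, KO over WT, was -0.33 (SE 0.16, adjusted p = 0.208 by edgeR), and -0.29 (adjusted p = 0.343) with run as a term. Counts of transcript ends can lie outside the deleted part of a gene, so this level does not check the genotype labels. In the hepatocyte-like cluster Xbp1 stood at 243 CPM in KO and 239 CPM in WT, the highest level among the 22 clusters tested.

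Across the whole embryo, genes of the liver fell in KO embryos. Albumin (Alb) fell by 3.74 on the log2 scale (SE 0.39, adjusted p = 0.0011, n = 5 and 4, edgeR), the apolipoprotein gene Apoa1 changed by -3.75 (SE 0.34, adjusted p = 8.81e-04) and the class I gene H2-Q10 fell by 4.63 (SE 0.38, adjusted p = 5.10e-04). In GRCm38 the protein-coding genes Alb, Apoa1 and H2-Q10 lie on chromosome 5 (90460897 to 90476602), chromosome 9 (46228580 to 46230466) and chromosome 17 (35470089 to 35474563). Of 15663 genes tested, 152 rose and 723 fell, and 4084 had an unadjusted p under 0.05. Among the genes that fell, 219 (30.3%) had their highest level in hepatocyte-like cells, against 4.3% of all genes tested, and 256 (35.4%) in erythroid-like cells, against 8.5%. Among the genes that rose, 61 (40.1%) had it in neuron-like cells, against 15.8% of all genes tested. Other large falls were those of Apoc4 (-5.15), Spp2 (-4.51), Apoh (-4.42), Lect2 (-4.34), the fatty acid binding gene Fabp1 (-4.27), Cyp2c68 (-4.04) and Aadac (-3.79), each also past the threshold with run as a term. The bone matrix gene Ibsp (-6.43) and the granulocyte protease gene Ctsg (-3.89) fell in the pooled test only, and with run as a term stood at -1.47 (adjusted p = 0.700) and -0.50 (adjusted p = 0.720). Among genes with an average of at least 10 CPM, the largest rises were those of mt-Ta (1.17), Pou2f2 (1.17), mt-Tq (1.12), the limb homeobox gene Shox2 (1.12, SE 0.19, adjusted p = 0.0081), Nr2f1 (1.11), mt-Tc (1.099), Fndc3c1 (1.08), Cacng7 (1.08), Dact3 (1.06), Lix1 (1.02), mt-Tp (1.02) and Zfhx3 (1.01). Of these 12, mt-Tq (0.79), Shox2 (0.80), Lix1 (0.70) and mt-Tp (0.66) still passed with run as a term. Mitochondrial transcripts made up 1.53% ± 0.071 of UMIs in KO and 1.28% ± 0.147 in WT units (exact permutation p = 0.0317).

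When run was a term, 14 genes rose and 325 fell, of which 278 were among the 875 called without it. Without WT1 and WT2 the counts were 5 and 241, and among the 7 units with Y-linked RNA 14 and 275. Fold changes within the second and last runs correlated across all genes tested (Pearson r = 0.826; genes are not independent replicates), and differed between these runs for 4 genes. Leaving out KO1 to KO5 in turn gave 32, 36, 13, 34 and 18 rises, and leaving out WT1 to WT4 gave 21, 29, 682 and 282. The falls numbered 410, 412, 258, 347 and 342 without KO1 to KO5, and 400, 396 and 1254 without WT1, WT2 and WT3.

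**Figure D1:**
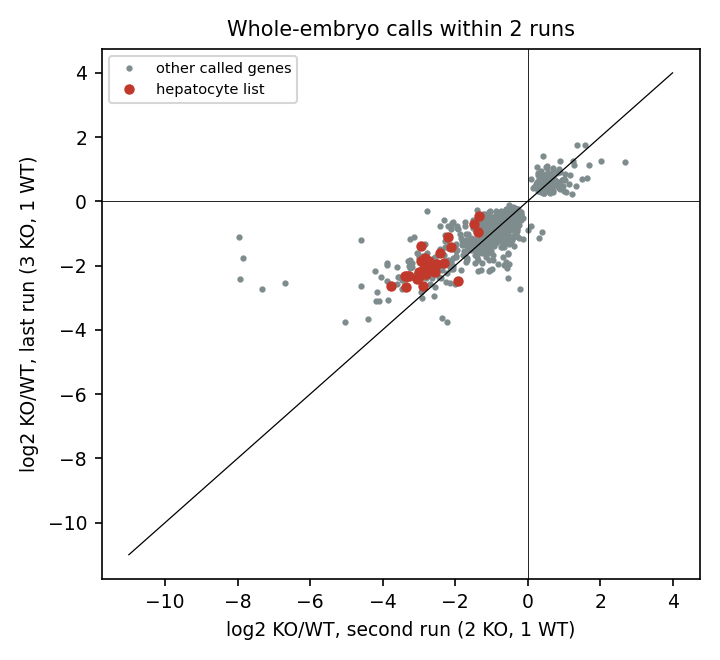
The log2 fold change, KO over WT, of each of the 875 genes that differed in the whole embryo is plotted for the second run (horizontal axis, 2 KO units and 1 WT unit) against the last run (vertical axis, 3 KO units and 1 WT unit), with genes of the hepatocyte list in red, the others in grey and the line of equal change in black. The genes were picked by a test on the units of both runs.

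Gene lists fixed before the data were examined gave the whole-embryo result by pathway and cell type. All 27 measured genes of the hepatocyte list fell (27 adjusted over the list alone), with a median log2 fold change of -3.14, among them Trf (-2.88) and Serpina1a (-3.50). With run as a term 25 fell. Of 22 non-globin erythroid genes 7 fell (13 adjusted over the list alone, median -0.78), including the red cell transcription factor genes Klf1 (-1.50) and Gata1 (-1.56), and with run as a term 14 fell. Of 49 XBP1 target genes of ER translocation and folding 5 fell and 1 rose (25 and 1 adjusted over the list alone, median -0.36): Ssr4 (-0.83), Sec11c (-1.16) and Tram1 (-0.51) fell, and Derl3, a gene of ER-associated degradation, rose (1.90, adjusted p = 0.0152; with run 1.59, adjusted p = 0.0992). After run was added, 1 XBP1 target gene fell. Of 33 genes of the ATF4-CHOP branch, which answers amino acid shortage and ER stress, 8 fell (12 adjusted over the list alone, median -0.31), such as Asns (-1.21) and Shmt2 (-0.69). Asns is also a leading gene of erythroid-like cluster 5, whose share of cells was lower, and within clusters 5 and 6 the score of this branch differed by 0.03 and 0.15 (exact permutation p = 0.825 and 0.429). Immediate-early and heat-shock genes fell in 10 of 20 cases (12 adjusted over the list alone, median -0.96), led by Fos (-3.03), Fosb (-3.38) and Junb (-2.64), and in 3 with run as a term. Of 10 granulocyte and mast cell genes 4 fell (5 adjusted over the list alone, median -1.06), Mpo (-1.92), Prtn3 (-1.43), Elane (-2.97) and Ctsg, and with run as a term edgeR called 0. Of 20 S phase genes 2 fell (14 adjusted over the list alone, median -0.40), Cdc6 (-0.78) and Tyms (-0.50). Of 14 epithelial genes Krt18 fell (-0.79; 10 adjusted over the list alone, median -0.84), and 22 sterol and fatty acid synthesis genes had a median of 0.31, with 8 higher and 1 lower at an unadjusted p under 0.05.

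Other lists passed as sets while edgeR called 0 of their members, also over the list alone. These were the 17 ATF6-branch chaperone genes (median -0.26; 6 with an unadjusted p under 0.05, 2 by DESeq2), 30 respiratory chain genes (-0.25; 11 and 4), 14 neural progenitor genes (0.72; 4 and 1), 20 neuron genes (0.50; 8 and 1) and 15 posterior Hox genes (0.77; 6 and 1). In all, 14 of 36 lists passed camera with its preset correlation, 10 lower and 4 higher in KO. With an estimated correlation 0 passed, 3 had an unadjusted p under 0.05, and fry called 9. The unadjusted p with an estimated correlation was 0.0224 for hepatocyte, 0.0256 for S phase, 0.0806 for immediate-early, 0.0810 for neural progenitor, 0.0907 for ATF4-CHOP, 0.0955 for XBP1 target, 0.131 for erythroid, 0.135 for sterol, 0.171 for epithelial, 0.224 for respiratory chain, 0.236 for neuron, 0.244 for posterior Hox, 0.345 for granulocyte and mast cell and 0.360 for ATF6-branch genes.

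KO embryos yielded fewer hepatocyte-like cells. Cells drawing at least 5% of their UMIs from 23 hepatocyte genes not past the threshold for all genes within the hepatocyte-like cluster made up 0.283% ± 0.054 (SD, n = 5) of KO cells and 2.40% ± 1.37 (SD, n = 4) of WT cells, a log2 ratio of -3.08. Each of the 5 KO units lay below the lowest WT unit (0.353% at most against 1.21% at least; exact permutation test, two-sided, p = 0.0159, the smallest that splits of 5 against 4 units allow). In the second run the shares were 0.298% and 0.276% in KO against 1.80% in WT, and in the last 0.203%, 0.286% and 0.353% against 1.21%. This measure was chosen after the data had been examined; 145 KO and 943 WT cells passed it, 109 cells lay within 1 percentage point of the threshold, and at 10% the log2 ratio was -3.89. It is not separate from the cluster below, in which 100% of these cells lay. With the 28 genes of the whole list 222 KO and 1066 WT cells passed 5%, of which 88.9% lay in the cluster, and the log2 ratio was -2.65. The deposited hepatocyte-like cluster (number 21, leading genes Afp, Alb and Rbp4) held 0.329% ± 0.069 of KO and 2.59% ± 1.43 of WT cells, a log2 fold change of -2.98 (SE 0.39, adjusted p = 4.98e-04 by edgeR; with run -2.27, adjusted p = 7.30e-04; within the second run -2.33 and the last -2.22). Its size is given second because 2 of its leading genes, Alb and Apoa1, themselves differed between the groups within it.

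Erythroid-like cells were lower in KO in 1 of the 3 clusters of that name. Cluster 5, led by Klf1, Pklr and the heme synthesis gene Cpox, held 2.22% ± 0.690 (n = 5) of KO and 14.97% ± 10.2 (n = 4) of WT cells, a log2 fold change of -2.75 (SE 0.47, adjusted p = 0.0022 by edgeR; with run -1.78, adjusted p = 0.0077). Cluster 6, led by the adult globins Hbb-bs and Hbb-bt, held 4.92% ± 1.29 and 9.69% ± 3.099 (-0.98, adjusted p = 0.0593; with run -1.22, adjusted p = 0.0274, and without WT1 -1.18, adjusted p = 0.0151). Cluster 9, led by the embryonic globins Hbb-bh1, Hba-x and Hbb-y, held 2.79% and 2.16% (0.36, adjusted p = 0.890; with run -0.13), and its value was 3.01 without WT3 and -0.16, -0.05 and -0.05 without KO1, WT1 and WT2. Its share of WT cells ran from 0.020% in WT1 and 0.028% in WT2 to 7.64% in WT3. Macrophage-like cluster 20 held 1.11% and 1.72% (-0.62, adjusted p = 0.284; with run 0.13). Unnamed cluster 10, led by the mast cell gene Cpa3 and by Cma1, Il2rg and Gzma, held 1.33% and 4.00% (-1.59, adjusted p = 0.0112; with run -0.85, adjusted p = 0.0656). Unnamed cluster 15, led by Ibsp, Cytl1 and Fos, held 0.065% and 4.70% (-5.97, adjusted p = 0.0097; with run -2.67, adjusted p = 0.0656), with 81.7% of its cells from WT1 and a value of -3.90 without WT1. Of 27 clusters 4 were lower and 0 higher in KO by edgeR; 1 was higher at an unadjusted p under 0.05, and 2 by the exact permutation test. With run as a term the lower clusters were 21, 5 and 6. By the exact permutation test the adjusted p was 0.0857 for clusters 21, 5, 10 and 15, so 0 passed. Without WT4 2 clusters were higher.

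**Figure D2:**
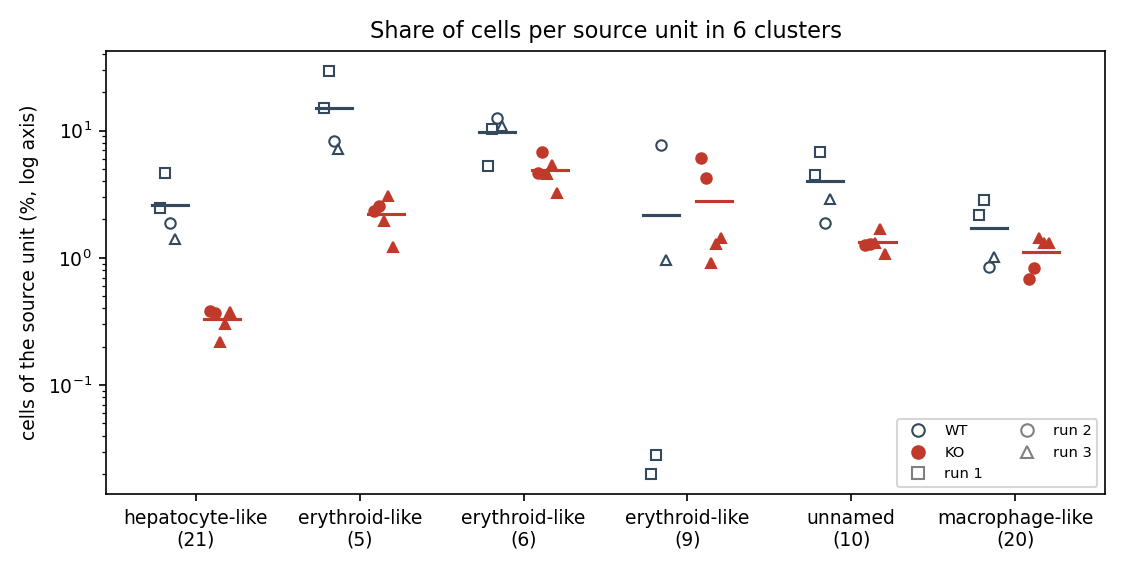
The share of each source unit's cells (percent, log axis) is plotted for 6 clusters, with WT units as open and KO units as filled symbols, the symbol shape giving the sequencing run and each bar the group mean. In hepatocyte-like cluster 21 the group means were 0.329% for KO and 2.59% for WT units, and all 5 KO units lay below the WT units.

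Within the hepatocyte-like cluster, genes of the ER stress response moved in different directions. Chaperone genes of the ATF6 branch rose, among them Hspa5, which encodes the ER chaperone BiP (log2 fold change 1.88, SE 0.19, adjusted p = 8.49e-06 by edgeR, n = 3 KO and 4 WT units), and Hsp90b1 (2.17, SE 0.23, adjusted p = 1.14e-05). Ddit3, which encodes the stress transcription factor CHOP, rose by 4.06 (SE 0.26, adjusted p = 5.73e-09). The ER translocation gene Sec61b fell (-1.78, SE 0.22, adjusted p = 5.26e-05), and so did the sterol synthesis gene Msmo1 (-2.36, SE 0.26, adjusted p = 1.46e-05). The protein-coding genes Hspa5, Ddit3 and Sec61b lie on chromosome 2 (34771970 to 34777547), chromosome 10 (127290774 to 127296288) and chromosome 4 (47474658 to 47483242) of GRCm38. The test covered KO1, KO3 and KO5, since KO2 and KO4 gave 12 and 18 cells of this cluster, under the minimum of 20. Of 4004 genes tested 74 rose and 72 fell, 699 had an unadjusted p under 0.05, and DESeq2 called 76 and 76. Once run was added, 83 rose and 74 fell, and 122 of the 146 genes were called in both. Leaving out 1 unit lowered the rises from 74 to 38 without KO1, 25 without KO5 and 45 without WT1, and the falls from 72 to 42 without KO1, 47 without KO3 and 26 without KO5.

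Derl3 (chromosome 10, 75893413 to 75895941) had 161 counts in KO and 2 in WT cells of this cluster, from 288322 and 1737752 UMIs, a ratio of 485 with a counting interval of 132 to 4041 (95%, counting error only). Trib3, a target of CHOP, rose by 5.08 (SE 0.65, adjusted p = 7.73e-05), with 29 and 5 counts, and the amino acid transporter gene Slc7a3 by 3.81 (adjusted p = 0.0025; 0.0568 without KO1). The lanosterol synthase gene Lss had 1 count in KO and 190 in WT cells, a ratio of WT over KO of 31.5 (counting interval 5.6 to 1252). For Insig1 (2 and 146 counts) the ratio was 12.1 (3.3 to 101), for Scd1 (2 and 133) 11 (3.0 to 92.1) and for Ifitm3 (2 and 144) 11.9 (3.2 to 99.6). Lss, Insig1 and Scd1 fell with adjusted p of 0.0013, 0.0035 and 0.0164 by edgeR, and 0.0530, 0.0812 and 0.204 without KO5. Ifitm3 fell at an adjusted p of 0.0391, but with run as a term its adjusted p was 0.0573, and it was 0.132, 0.0927 and 0.153 without KO1, KO3 and KO5.

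Of the fixed lists, 4 passed in this cluster with an estimated correlation as well. Of 40 XBP1 target genes 9 fell and 1 rose (26 and 3 adjusted over the list alone, median -0.73; adjusted p = 0.0106 with an estimated correlation). Serp1 (-1.45) and Ostc (-1.05), both of the translocation machinery, were among the falls, and Derl3 was the rise. Of 14 ATF6-branch genes 9 rose (11 adjusted over the list alone, median 1.49; adjusted p = 0.0124 with an estimated correlation), including Sdf2l1 (2.04) and Manf (1.63). Of 22 ATF4-CHOP genes 12 rose (17 adjusted over the list alone, median 1.07; adjusted p = 0.0124 with an estimated correlation), including Slc3a2 (1.81) and Atf5 (1.64). Of 20 sterol and fatty acid synthesis genes 12 fell (17 adjusted over the list alone, median -1.76; adjusted p = 0.0106 with an estimated correlation), including Cyp51 (-2.87), Fdps (-1.86) and Sqle (-1.96). Hypoxia and glycolysis genes rose in 5 of 18 cases (9 adjusted over the list alone, median 0.97), Pkm (1.66), Ddit4 (1.78), Eno1 (1.13) and Aldoa (1.03) among them, with p = 0.1105 for the list with an estimated correlation. The hepatocyte list (27 tested, 4 lower, 10 adjusted over the list alone; Ttr -0.87 and Fabp1 -1.45, with Alb and Apoa1, leading genes of the cluster, as the other falls), the respiratory chain list and the S phase list passed with the preset correlation alone (p = 0.135, 0.228 and 0.0530 with an estimated correlation). For the latter pair edgeR called 0 of 30 and 0 of 16 genes, 6 and 1 had an unadjusted p under 0.05, and DESeq2 called 1 and 0. Junb (-2.17) and Fos (-2.38) also fell in these cells, and with run as a term their adjusted p was 0.0536 and 0.215. In all, 8 of 19 lists passed, 5 by fry.

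**Figure D3:**
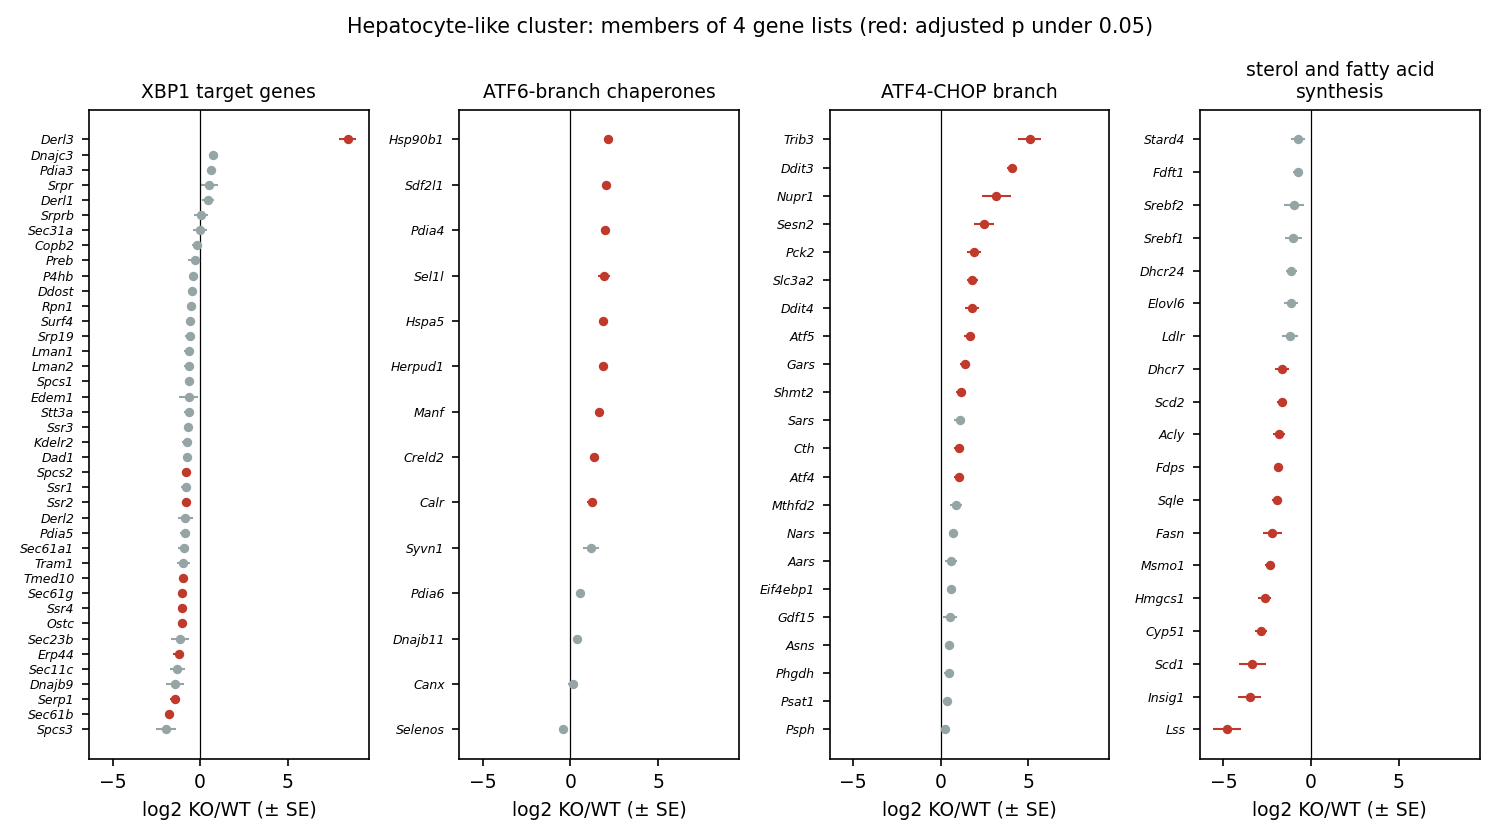
Each point is a reported gene of the XBP1 target, ATF6-branch, ATF4-CHOP or sterol and fatty acid synthesis list, with its log2 fold change, KO over WT, in the hepatocyte-like cluster on the horizontal axis, bars of 1 SE and red for an adjusted p under 0.05 by edgeR. XBP1 target and sterol synthesis genes had medians of -0.73 and -1.76, and ATF6-branch and ATF4-CHOP genes 1.49 and 1.07. For genes with 1 to 3 counts in a group, Derl3, Lss, Insig1 and Scd1 among them, the plotted fold depends on the prior count.

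The same 3 stress lists were scored per source unit as the mean log2(CPM + 1) of their genes. Run was not a term in these comparisons. In the hepatocyte-like cluster the XBP1 target score was 6.02 ± 0.157 (SD, n = 3) in KO and 6.86 ± 0.123 (SD, n = 4) in WT, the ATF6 score 8.22 ± 0.471 and 7.36 ± 0.073, and the ATF4-CHOP score 5.91 ± 0.290 and 4.86 ± 0.176. Differences were -0.84, 0.86 and 1.05, each with an exact permutation p of 0.0571, the smallest that 35 splits allow. With all 9 units, admitted at 10 cells or more after the data had been examined, they were -1.07 (exact permutation p = 0.0159), 0.57 (p = 0.175) and 0.82 (p = 0.0317), with adjusted p over 22 clusters of 0.175, 0.540 and 0.210. The units so added, KO2 and KO4, held 12 and 18 cells, and the KO SD of the XBP1 target score rose to 0.447. Among the other clusters the smallest p of the XBP1 target score was that of chondrocyte-like cluster 8 (-0.50, exact permutation p = 0.0159, adjusted p = 0.2095), and of the ATF4-CHOP score that of epithelium-like cluster 13 (-0.50, exact permutation p = 0.0159, adjusted p = 0.251). A lower XBP1 target score was not confined to the hepatocyte-like cluster, though the difference was largest there. The score was lower in KO in every other cluster tested except 3, 22 and 23 (0.18, 0.05 and 0.09). With log2(CPM + 10) it was lower in these as well (-0.04, -0.03 and -0.04).

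In the other clusters, genes of hepatocytes and red cells fell together with immediate-early genes. Albumin was lower in KO in neuron-like cluster 2 (-3.46, SE 0.30, adjusted p = 4.14e-05 by edgeR; with run -2.93), neural progenitor-like cluster 4 (-3.41), chondrocyte-like cluster 8 (-3.45), unnamed cluster 1 led by Twist2 and Prrx1 (-3.56) and unnamed cluster 3 (-2.84). Apoa1 fell by 3.21 in cluster 2 and by 2.69 in cluster 3, Afp by 3.06 in cluster 2 and by 2.21 in cluster 3, and Apoa2 by 2.32 in cluster 3. Fos fell by 3.92 in cluster 8 (SE 0.48, adjusted p = 4.32e-04; with run -2.91), and changed by -3.27 in cluster 1, -3.37 in cluster 4 and -3.17 in cluster 2 (with run -2.05, adjusted p = 0.0646). Junb fell by 4.22 and Egr1 by 3.24 in cluster 8, and Junb by 3.31 in cluster 1 (with run -1.54, adjusted p = 0.229). The 3 largest rises of cluster 8, Dnm3os (1.56), Hist1h2ag (1.32) and Sox4 (0.95), passed in the pooled test and not with run as a term (adjusted p = 0.206, 0.274 and 0.272). In cluster 4 mt-Tm rose by 1.14 (with run 0.96, adjusted p = 0.0220).

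Over 21 other clusters there were 19 rises and 270 falls, counted as gene and cluster pairs. Of the falls 114 were of 16 genes at least 10-fold higher in hepatocyte-like cells than in the cluster tested. Another 52 were of 20 genes at least 10-fold higher in an erythroid-like cluster, 34 of 7 immediate-early genes and 70 of 67 other genes. Of the rises 6 were of mt-Tm and mt-Ti. Hepatocyte list genes summed to 124 to 320 CPM in neuron-like, neural progenitor-like, skeletal muscle-like and chondrocyte-like cells of the KO units and to 782 to 1736 CPM in those of the WT units. With run as a term 12 pairs rose, and without WT1 and WT2 5 rose and 159 fell. Rises numbered 11, 6, 11, 8, 4, 5, 109 and 254 without KO1, KO3, KO4, KO5, WT1, WT2, WT3 and WT4, and falls 161 and 479 without KO3 and WT3. In cardiomyocyte-like cluster 22 edgeR and DESeq2 called 0 genes, and 101 had an unadjusted p under 0.05.

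The number of genes per cell, a rough measure of how diverse a cell's transcripts are, was not past the threshold at any depth tested. After thinning to 500 UMIs, with 0 cells left out, the median cell held 412 ± 5.58 genes in KO (SD, n = 5) and 410.7 ± 7.10 in WT (SD, n = 4), a difference of 1.38 (exact permutation test, two-sided, p = 0.730). Without thinning the medians were 694 and 692. Leaving out erythroid-like clusters turned the difference to -3.03 (exact permutation p = 0.365), and leaving out WT2 to -1.56. It was 4.23 without WT1. At 1000 UMIs, with 25479 KO and 22059 WT cells left out, the difference was 22.03 (716 and 694 genes, exact permutation p = 0.127), and without erythroid-like clusters 0.72.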

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

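The comparison of scores between clusters at 10 cells or more per unit was chosen after the scores at 20 cells had been seen; the search for single units far from their group was planned. The latter covered 66 groups of 4 or 5 units, in which chance alone sets apart about 1 in 20, or 3.3 groups, and it found 4.

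The bone matrix gene Ibsp stood at 149 CPM in WT1 and at most 7.19 CPM in the other WT units. Unnamed cluster 15, of which Ibsp is the first leading gene, held 15.3% of the cells of WT1 and at most 2.70% of those of another WT unit. The embryonic globin cluster 9 held 7.64% of the cells of WT3 and at most 0.97% of those of another WT unit. In KO1 and KO2, of the same run as WT3, it held 6.1% and 4.2%. In WT1 and WT2 it held 0.020% and 0.028%, 2 cells each. The mitochondrial tRNA gene mt-Tq stood at 15.9 CPM in WT4, with the nearest other WT unit at 9.07 CPM. No explanation of these 4 outlying values was tested.

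The KO effect on the 3 stress scores differed between the hepatocyte-like cluster and the mean of the other clusters, tested within source units. KO minus WT of that difference was -0.81 for XBP1 target genes (exact permutation p = 0.0159), 0.79 for ATF6-branch genes (exact permutation p = 0.0476) and 1.02 for ATF4-CHOP genes (exact permutation p = 0.0159). Against each of the 21 other clusters it was negative for XBP1 target genes and positive for ATF6-branch and ATF4-CHOP genes. With 20 cells or more per unit, KO2 and KO4 left out, the values were -0.68, 0.98 and 1.11, each at the smallest p that 35 splits allow, 0.0571. With log2(CPM + 10) in place of log2(CPM + 1) they were -0.42, 1.06 and 0.95, at the same p.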

How the results depend on the processing

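Run as a term, the units with Y-linked RNA alone, 10 cells or more per unit and genes per cell without erythroid-like clusters were chosen after the results were seen; the other alternatives were planned. Where no cause is given below, the cause was not tested. In the whole embryo, against 152 rises and 723 falls, DESeq2 gave 539 and 1373, run as a term 14 and 325, no WT1 and WT2 5 and 241, units with Y-linked RNA 14 and 275, no erythroid-like clusters 16 and 361, libraries as units with a random block 1009 and 1249, and no filter on low counts 82 rises; the settings without some units also test fewer samples. In the hepatocyte-like cluster, against 74 and 72, units with Y-linked RNA gave 38 and 42. In the other clusters, against 19 and 270, DESeq2 gave 82 rises, run as a term 12 rises and 244 falls, and no WT1 and WT2 5 and 159. Of the lists, against 14 in the whole embryo and 8 in the hepatocyte-like cluster, 0 and 4 passed with an estimated correlation and 9 and 5 by fry. Clusters with a lower share, 4 by edgeR, numbered 2 among units with Y-linked RNA and 0 by the exact permutation test, whose adjusted p for the hepatocyte-like cluster was 0.0857 at a log2 ratio of -2.98. At 10 cells or more per unit the XBP1 target score difference was -1.07 and the ATF4-CHOP one 0.82. Both had an exact permutation p under 0.05, which 35 splits do not allow, and neither passed after adjustment over clusters. The added KO2 and KO4 held 12 and 18 cells, and the KO SD of the XBP1 target score was 0.447 against 0.157 without them. With log2(CPM + 10) at 20 cells or more the XBP1 target difference was -0.59. Genes per cell changed sign without erythroid-like clusters (-3.03) and without WT2 (-1.56). The share of cluster 9 changed sign without WT1 and WT2 (-0.63), with run as a term (-0.13), among units with Y-linked RNA (-0.85) and without KO1 (-0.16), WT1 (-0.05) or WT2 (-0.05), and that of cluster 20 without WT1 and WT2 (0.26) and with run as a term (0.13). Without WT3 the log2 fold change of cluster 9 was 3.01, not past the threshold. No cells of the matrices lay outside the annotation, so adding such cells changed nothing.

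The source numbers do not pair the units: same-numbered KO and WT units deviated from their group means with correlations of -0.41, -0.05, -0.34 and 0.04, and not every unit correlated best with its own number. With the replicate number as a block, KO5 left out, the whole embryo gave 2 rises and 149 falls, the hepatocyte-like cluster 11 and 9, the other clusters 4 and 130, and 2 clusters were lower.

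Leaving out 1 unit at a time gave 13 to 682 rises and 258 to 1254 falls in the whole embryo, an Xbp1 log2 fold change of -0.42 to -0.23, 25 to 106 rises and 26 to 92 falls in the hepatocyte-like cluster, 4 to 254 and 161 to 479 in the other clusters, 13 to 21 lists in the whole embryo and 7 to 10 in the hepatocyte-like cluster, 0 to 2 clusters higher and 4 to 6 lower, a hepatocyte-like share of -3.18 to -2.54, and -1.56 to 4.23 genes per cell. Of 662 further values for named genes and clusters, 502 kept their direction and side of the threshold, 149 kept the direction and lost the threshold, 3 passed it and 8 changed sign. Depth limits the hepatocyte-like cluster, with 288322 UMIs in KO units against 1737752 in WT units.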

Other observations

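Of the tests below, run as a term for the hepatocyte-like share and for immediate-early genes, the ratio of hepatocyte-like to erythroid-like cells, and the splits within runs were chosen after the results were seen. The others had their bounds set before. The share of cells by UMIs was nonetheless a measure added after the data had been examined. The genes in the next paragraph were chosen after their values were seen.

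In macrophage-like cluster 20, 15 genes were lower in KO units in the pooled test, with log2 fold changes of -1.41 for Ccl2, -1.87 for Ccl4, -1.33 for Ccl7 and -0.93 for Ccl12 (adjusted p = 0.0130, 0.0130, 0.0174 and 0.0428 by edgeR), but with run as a term their adjusted p was 0.218, 0.534, 0.429 and 0.280. The immediate-early genes Dusp1 (-2.03) and Jun (-0.94) fell in the same cluster, and no list of chemokine genes was tested. Unnamed cluster 10, led by Cpa3 and Cma1, had more RNA of the lipoxygenase gene Alox15 (4.28, adjusted p = 0.0030; with run 3.67, adjusted p = 0.0363) and of the NADPH oxidase gene Cybb (1.92, adjusted p = 0.0030; with run 2.14, adjusted p = 0.0163). Unnamed cluster 3, whose leading genes join the embryonic globin Hbb-y to Twist2 and Prrx1, had less RNA of Gata1 (-1.69), Klf1 (-1.24) and Slc4a1 (-1.21), each also past the threshold with run as a term. In pericyte/smooth muscle-like cluster 16 the LIM homeobox gene Isl1 was higher (1.97, adjusted p = 0.0244; with run 1.62, adjusted p = 0.371).

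The 22 other fixed lists did not pass in the whole embryo. Single members of some of them passed by edgeR. Of 13 forebrain genes Otx2 (0.91) and Six3 (0.93) rose and Neurod6 fell (-1.68); of 10 interferon genes Usp18 (-1.67) and Bst2 (-1.21) fell; of 12 endoderm genes Hhex (-1.07) and Sftpc (-4.12) fell. The glycolysis gene Pdk1 (-0.73) and Ibsp of the osteoblast list fell, and the nephron gene Six2 (0.96) and the pericyte gene Notch3 (0.85) rose. Of these, Hhex passed with run as a term. The megakaryocyte list is not reported here. EdgeR called 0 members of the lists that follow, with counts at an unadjusted p under 0.05, and by DESeq2, of 7 and 0 for 13 cartilage, 5 and 2 for 22 G2 and M phase, 5 and 4 for 15 p53 target, 3 and 1 for 21 fibroblast matrix, 3 and 1 for 9 neural crest, 2 and 0 for 17 macrophage, 2 and 1 for 16 skeletal muscle, 2 and 0 for 12 heart muscle, and 1 and 1 for 17 endothelial genes. For 9 transcripts cut by IRE1, 3 embryonic globin, 4 adult globin, 9 mitochondrially encoded and 4 sex-linked genes both counts were 0. For adult globin and pericyte genes camera's direction was up while the medians were -0.08 and -0.23.

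Other splits of the same units into groups of the same sizes were set beside each count of calls. Among splits that exchange units across runs, the real one alone gave as many calls for 3 of the counts. These were the whole-embryo genes (1 of 100 splits, 875 calls against at most 24), the clusters by share of cells (1 of 100, 4 against 2), and the hepatocyte-like cluster genes (1 of 35, 146 against 30). Such splits treat units as exchangeable across runs. The first run holds WT units alone, so a difference between runs could also add to these counts, and chance is not excluded by them. For the genes of the other clusters 2 of 100 splits gave as many, a share under 0.05, the bound at which chance would be set aside. Chance is still not excluded there, because a split that follows the runs gave more calls. This highest other split gave 325 calls, against 289 for the real one. It set KO1, KO2, KO4, WT3 and WT4 against the rest, which keeps the second run on 1 side and the first on the other; with run as a term the other clusters gave 12 rises and 244 falls. Splits that exchange units within runs alone, with run as a term, are too few for a share under 0.05. The real split was 1 of 12 with as many for the whole-embryo genes (339, highest other 0), the clusters by share of cells (3, highest other 0) and the genes of the other clusters (256, highest other 137), and 1 of 6 for the hepatocyte-like cluster genes (157, highest other 38). Chance cannot be excluded for the number of lists past the threshold: in the whole embryo 71 of 100 splits gave 14 or more, up to 25, and in the hepatocyte-like cluster 11 of 35 gave 8 or more, up to 11.

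KO units held fewer hepatocyte-like cells, by cluster and by UMIs, which are not separate measures since 100% of the cells found by UMIs lay in the cluster. With run as a term the log2 fold change of the share was -2.27 (SE 0.31), below -1 by more than 2 SE, which argues against the sequencing run as the whole cause. Cells placed in other clusters because their marker genes fell stay open, although the share by UMIs had a log2 ratio of -3.08: the genes it used leave out just those past the threshold for all genes, so that some of them also fell, and were picked in cells that had stayed in the cluster, so the bound set beforehand, -1, could not exclude it. Less liver among the cells sampled also stays open, since the log2 ratio of hepatocyte-like to erythroid-like cluster 5 cells differed by -0.26 (exact permutation p = 0.492), while the ratio to clusters 5 and 6 together differed by -1.08 (exact permutation p = 0.0317), past the bound of 1 by less than the SD of the KO units (0.53), and that to macrophage-like cells by -2.33 (exact permutation p = 0.0159). A smaller number of hepatocytes in embryos without Xbp1 is the biological hypothesis, and these data do not separate it from that pair.

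Genes of hepatocytes and red cells were lower in KO in clusters of other types. If free RNA from hepatocyte-like cells was the source, the counts of their genes in neuron-like, neural progenitor-like, skeletal muscle-like and chondrocyte-like cells follow those in the hepatocyte-like cluster of the same unit, and the median Pearson r over the 9 units was 0.912 (across list genes, which are not independent replicates), above the 0.8 set beforehand. It was 0.957 to 0.979 in the WT units and 0.706 to 0.912 in the KO units, 3 of which lay under 0.8, so that the reading rests on the WT units more than on the KO units. For erythroid genes it was 0.782, between the bounds of 0.8 and 0.5, so that source stays open. Hepatocyte-like cells placed in these clusters, or cells holding RNA of more than 1 type, would give the same pattern, so r does not single out free RNA. A change of these genes within the clusters themselves was not tested.

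Immediate-early genes were lower in KO in 34 gene and cluster pairs, of 7 genes in 17 clusters, and these genes also rise while tissue is dissociated. With run as a term the median log2 fold change went from -2.52 to -1.50, a ratio of 0.597, between the bounds of 0.5 and 0.75, and 15 pairs still passed. The sequencing run may thus account for part of the difference. Whether it accounts for all of it stays open, since these pairs were picked by a test on the same units. Of the 20 genes of the fixed list 3 passed with run as a term in the whole embryo, Fos at -1.56 (SE 0.30, adjusted p = 0.0260) among them. Within runs, Fos stood at 94.1 CPM in WT3 against 30.4 and 41.5 in KO1 and KO2. In the last run it stood at 110 CPM in WT4 against 21.9, 45.0 and 47.1 in KO3 to KO5. The list's share of UMIs, which also counts its heat-shock genes, was 0.359% in WT3 against 0.355% and 0.381% in the KO units of its run. It was 0.454% in WT4 against 0.428% to 0.430%. Each of these runs holds 1 WT unit, and a difference in the handling of single units was not tested.

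A pair of further hypotheses was tested, neither of which was settled. A shift in cluster shares alone, with the WT profile of each cluster, predicted at least 0.5 times the measured log2 fold change for 47.2% of the 723 genes that fell in the whole embryo (95% interval 43.5 to 50.9), near the bound of 50% under which it would be set aside. A segment of other DNA carried along with the Xbp1 deletion would raise the share of genes called near it, and within 10 Mb of Xbp1 6 of 87 genes tested were called, an odds ratio of 1.245 (95% interval 0.442 to 2.840, Fisher's exact p = 0.636), whose interval includes the bound of 2. The readings of these 2 tests, and of the one on marker genes above, were changed to open after their values had been seen; by the bounds as first written all 3 explanations would have been set aside. They were changed because the intervals include the bounds and because the list left out called genes.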
